A study of Mus musculus with 12 samples.

How the data were processed

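Gene expression was measured in 12 samples of sorted mouse haematopoietic cells, 1 array each, in 4 groups of 3. Per the labels, RNA of double-sorted cells was extracted, amplified with a NuGEN whole-transcript kit, labelled with biotin and hybridised to Affymetrix Mouse Gene ST arrays. The deposited values are log2 expression per probe set, normalized across arrays by the authors, and limma, affy and RMA are named in the submitters' processing notes with no versions. Software settings, genome build and probe annotation of that step are not given in the sources used here. The scale was checked on the values, whose array medians lay between 5.87 and 5.94. Scanner files and scan dates were not used here, and neither was the fetal liver CD48+LSK group that the design text names. Every value table column was used.

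Probe sets were named through the platform annotation supplied with the data. Of 28940 probe sets, 21789 had 1 gene symbol, 1621 had several and 5530 were not in that annotation. The tests used probe sets with 1 symbol and, for the 999 genes with more than 1 such probe set, the one with the highest mean over the 12 arrays, which gave 19938 genes with no filter on intensity. Gene order and chromosome came from a RefSeq gene table of assembly GRCm38.p6, which was used only for names and neighbours, and 19917 genes were placed.

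Groups came from the sample labels. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), so that the 4 groups shared 1 estimate of the spread. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 19938 genes, and genes passed at an adjusted p under 0.05. Adjusted p-values of genes in the text are limma's, also where an array was left out. The 3 comparisons were Sox17-labelled against adult CD48+LSK cells, fetal liver against adult HSCs, and adult HSCs against adult CD48+LSK cells. Values are log2 fold changes with the standard error of the model, and folds are 2 to the power of these.

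In total 24 gene lists were fixed, with 433 memberships (414 genes), of which 381 were measured. They cover HSC-enriched genes, multipotent and lymphoid-primed progenitor genes, Hox and haematopoietic transcription factors, Lin28 and other fetal-stage regulators, imprinted growth genes, the cell cycle, quiescence, immediate-early and stress genes, interferon response, MHC, p53, Notch, Wnt, endoderm and ribosomal protein genes. Lists of the cell types a sort could also hold covered erythroid, megakaryocyte, granulocyte and monocyte, mast cell, B cell, T and NK cell, endothelial, hepatocyte and stromal genes. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists of a comparison, and again with the correlation estimated per list. Of the called lists, 6 of 10 in the Sox17-labelled comparison (HSC, progenitor, quiescence, MHC, megakaryocyte and endothelial genes), 5 of 10 between fetal liver and adult HSCs (Lin28, imprinted, MHC, megakaryocyte and endothelial genes) and 8 of 13 between adult HSCs and adult CD48+LSK cells (HSC, progenitor, imprinted, MHC, megakaryocyte, mast cell, endothelial and stromal genes) kept the call with the estimated correlation. Members were also counted after adjustment over the list alone, and again with each array left out. Signals are called dim where a group mean lay under all array medians. The alternative with dim genes left out used another rule. It dropped genes whose mean over all arrays lay under the median of these means. Genes with a dim mean in some group, such as Sparc, could thus stay in that alternative. List calls under it therefore do not show that a call holds without dim signals. The fry test was run as an alternative.

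Named genes followed a rule: Sox17; the 8 largest rises and 8 largest falls among genes that passed and whose 3 against 3 arrays did not overlap; up to 4 members with the smallest p of each list described; and the 6 genes in each direction with the largest shared change in the Sox17-labelled and fetal comparisons. Predicted or unnamed loci, olfactory receptors, microRNAs, immunoglobulin and T cell receptor segments and small RNAs were only counted (31 rises and 16 falls in the Sox17-labelled comparison, 16 and 21 in the fetal one, 9 and 12 in the adult one). Groups, tests, lists, the naming rule and most alternatives were chosen before the data were examined.

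Changes were compared across genes by Pearson's r, Spearman's rho and the covariance, with overlaps of calls set against those of independent lists. For the comparison pair that shares the adult CD48+LSK arrays, unchanged groups were simulated against these arrays in 1000 draws. Calls were also simulated in 50 draws, which had means of 0 and 0.02 calls per comparison, too few to measure a shared overlap. Sets of 200 genes from the fetal comparison, and of 100 and 500, were tested with camera, and these p-values were not adjusted. The fetal score was tested by exact permutation of 6 arrays.

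The steps were tested on simulated data in which 200 of 19938 genes were changed by a log2 of 0.5, 1 or 2. The measured endothelial list genes were also raised by a log2 of 1, and their calls are not counted as false. Noise was drawn independently for each gene with no array set apart, so the false calls may not describe these data. For Sox17-labelled against adult CD48+LSK cells 16.4%, 77.6% and 97.0% of the genes changed by 0.5, 1 and 2 were recovered, with 6 false calls in 149. For fetal liver against adult HSCs 22.4%, 74.6% and 98.5% were recovered (8 false of 147), and for adult HSCs against adult CD48+LSK cells 19.4%, 77.6% and 97.0% (12 of 154). The precision is thus that of 3 arrays a group, and changes well under 2-fold were mostly missed.

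Alternatives were all probe sets with 1 symbol, leaving out dim genes, cyclic loess normalization, median centring, fitting only the compared groups, the replicate number as a block, eBayes with trend and robust, array weights, a minimum log2 change of 1, other set sizes and set tests, and leaving out each array in turn. A repeated quantile normalization and a term for Y-linked transcripts (the mean of Eif2s3y, Kdm5d and Uty), and the split of the shared adult CD48+LSK arrays in 6 ways, were added after the data were seen.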

Results

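Gene expression was measured on 12 Affymetrix Mouse Gene ST arrays of sorted haematopoietic cells from C57BL/6 mice, in 4 groups of 3 arrays. Haematopoietic stem cells (HSCs) were sorted from fetal liver at embryonic stage E16.5 and from adult bone marrow at 8 weeks, in both cases as CD150-positive, CD48-negative cells of the LSK phenotype, which lacks lineage markers and carries Sca1 and Kit. Adult bone marrow CD48+LSK cells, a gate that holds multipotent progenitors, were sorted at the same age. The fourth group held CD48+LSK cells that the labels call Sox17-expressing, taken 12 weeks after transplant from recipients of marrow infected with a Sox17 retrovirus. Sox17 encodes an Sry-related transcription factor that acts in endoderm, endothelium and fetal HSCs. The labels describe the 3 arrays of a group as independent aliquots and do not say whether these came from separate animals, so the p-values measure the spread between these aliquots. The number of arrays limits the precision.

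Adult CD48+LSK replicate 2 stood apart from the other 11 arrays. The interquartile range of its log2 values was 2.75, against 3.13 to 3.31 on the others, and its Pearson correlations with them over all probe sets ran from 0.951 to 0.967, against 0.964 to 0.990 among the other 55 pairs. Xist, the RNA that coats the inactive X chromosome, was at log2 4.74 on this array and the Y-linked gene Eif2s3y at 8.76. The other adult CD48+LSK arrays and the Sox17-labelled arrays had Xist between 11.75 and 12.15 and Eif2s3y between 3.28 and 3.48. All 3 fetal liver HSC arrays carried both transcripts (Xist mean 11.20, SD 0.192, and Eif2s3y 7.21 to 8.79), and the adult HSC arrays ranged from Xist 11.76 with Eif2s3y 5.93 to Xist 5.37 with Eif2s3y 9.58. Within the adult HSC and the adult CD48+LSK group, these differences argue against aliquots of 1 pool of cells.

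The Sox17 probe set did not separate the Sox17-labelled arrays from the rest. It read log2 4.88, 4.91 and 4.67 on the Sox17-labelled arrays and 4.88, 4.52 and 4.56 on the adult CD48+LSK arrays, and all 12 arrays lay between 4.19 and 4.94. The difference was 0.17 ± 0.160 (SE, n = 3 per group, limma adjusted p = 0.721). Between fetal liver and adult HSCs it was 0.28 ± 0.160 (adjusted p = 0.473), and between adult HSCs and adult CD48+LSK cells −0.14 ± 0.160 (adjusted p = 0.793). All values of the probe set lay under the array medians (5.87 to 5.94), so its signal was dim in every group. Whether the probes lie within the retroviral insert is not given in the sources used here, so the group is named by its label throughout.

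The comparison of Sox17-labelled with adult CD48+LSK cells addresses what forced Sox17 expression changes in adult progenitors, according to the series title and design. Krt24, a keratin gene, rose 132-fold (log2 7.04 ± 0.158, SE, n = 3 per group), and Cdh5, the VE-cadherin of endothelial junctions, rose 59.9-fold (5.91 ± 0.249). Trap1a, which encodes a tumour rejection antigen, rose by 5.11 ± 0.161, the matrix glycoprotein gene Sparc by 4.82 ± 0.197, the tetraspanin gene Tspan8 by 4.6 ± 0.268, the tight junction gene Tjp1 by 4.50 ± 0.289, Palmd by 4.42 ± 0.247 and the calcium-binding protein gene S100a16 by 4.39 ± 0.183. Dntt, the terminal transferase of lymphoid precursors, fell by 5.35 on the log2 scale (SE 0.212), to a level 40.8-fold lower, and Emb fell by 4.17 (SE 0.220), 18.0-fold lower. Cd52 (−3.86 ± 0.410), Wfdc17 (−3.47 ± 0.377), the CD48-binding receptor gene Cd244a (−3.30 ± 0.157), the tetraspanin gene Cd53 (−3.30 ± 0.419), the transcriptional cofactor gene Eya1 (−3.12 ± 0.261) and the granule protein gene Nkg7 (−2.90 ± 0.188) also fell. The largest limma adjusted p among these 16 genes was 0.00049, for Cd53. For 8 of the 16 the lower group mean lay under all array medians (5.87 to 5.94): Krt24 (4.58), Cdh5 (4.77), Trap1a (3.99), Sparc (5.70), Tspan8 (5.69) and Palmd (4.80) on adult CD48+LSK arrays, and Dntt (4.81) and Eya1 (4.58) on Sox17-labelled arrays. Their changes were taken against dim signals, so their size is uncertain.

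**Figure D1:**
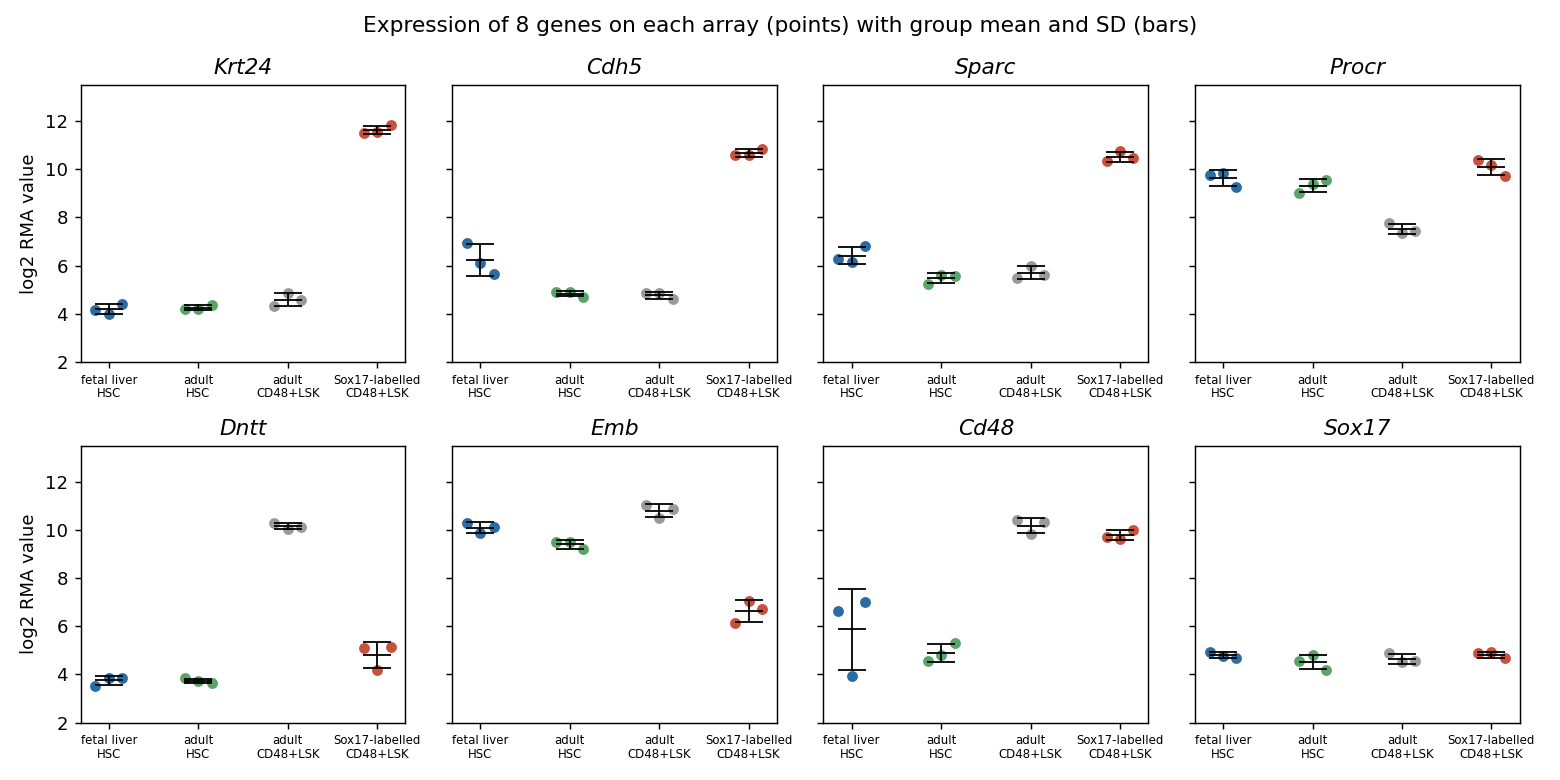
Log2 RMA values of Krt24, Cdh5, Sparc, Procr, Dntt, Emb, Cd48 and Sox17 on each of the 12 arrays, by group, with points for arrays and bars for the group mean and SD. Krt24 rose 132-fold and Dntt was 40.8-fold lower in the Sox17-labelled group than in adult CD48+LSK cells, while the Sox17 probe set stayed between 4.19 and 4.94 on all 12 arrays.

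Genes enriched in HSCs rose together in the Sox17-labelled cells. Of 21 measured members of the HSC list, 11 rose and 0 fell (12 and 1 adjusted over the list alone). Procr, whose product marks HSCs, rose 5.94-fold (log2 2.57 ± 0.212), Mllt3, a regulator of HSC maintenance, 4.63-fold (2.21 ± 0.169), the von Willebrand factor gene Vwf 5.61-fold (2.49 ± 0.165), and the adhesion molecule gene Esam 8.47-fold (3.08 ± 0.198). The mean log2 change of the list was 0.93 (limma camera, adjusted p = 9.65e-13, and 0.00484 with an estimated correlation). Slamf1, which encodes the CD150 used to sort HSCs, was not among the genes called (0.34 ± 0.173, adjusted p = 0.393). Cd48, the marker on which both groups were sorted, was at −0.39 ± 0.595 (adjusted p = 0.851). The HSC-list genes that rose numbered 10 or 11 with 1 array left out.

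Genes of multipotent and lymphoid-primed progenitors moved the other way. Of 15 measured, 8 fell and 0 rose (12 and 0 adjusted over the list alone), among them Dntt, Emb, Cd244a, the leukocyte actin-binding protein gene Lsp1 (−2.56 ± 0.165) and the cytokine receptor gene Flt3 (−1.14 ± 0.151). The list mean was −1.68 (camera adjusted p = 8.61e-17, and 0.00202 with an estimated correlation). Genes of major histocompatibility complex (MHC) proteins fell in 5 of 9 measured (6 over the list alone), with the class II genes H2-Ab1 5.86-fold lower (−2.55 ± 0.157), H2-Aa at −2.06 ± 0.299 (dim in Sox17-labelled cells, mean 5.53) and H2-Eb1 at −0.92 ± 0.156, and the class I-like gene H2-M3 at −0.78 ± 0.144. The MHC list mean was −0.88 (adjusted p = 1.01e-06, and 0.0116 with an estimated correlation). Leaving out any 1 array left 8 progenitor genes and 4 to 6 MHC genes lower.

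Endothelial genes had the highest list mean of the 24 lists in this comparison, 1.29 (camera adjusted p = 1.83e-15, and 0.000427 with an estimated correlation). Of 21 measured, 10 rose and 0 fell (12 and 0 adjusted over the list alone). Besides Cdh5 and Esam, the endothelial surface protein gene Ecscr rose 14.8-fold (3.88 ± 0.210) and the receptor gene Tie1 4.96-fold (2.31 ± 0.111). Esam, Vwf and Tek also belong to the HSC list, so these 3 genes count in both lists. Endothelial risers numbered 8 to 10 with 1 array left out. Of the 10 risers, 8 stood above adult HSCs too, with Cdh5 higher by 5.84, Ecscr by 2.74, Egfl7 by 2.39 and Pecam1 by 1.78 on the log2 scale. Among the 11 HSC-list risers 2 stood above adult HSCs, and among all 595 genes that rose 279 did.

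Megakaryocyte and platelet genes rose in 6 of 17 measured, with 0 falling (8 and 0 over the list alone). Vwf led them, followed by Mmrn1, which encodes a platelet granule protein (2.07 ± 0.245, from a dim mean of 4.70), the platelet integrin gene Itgb3 (1.54 ± 0.176) and the tetraspanin gene Cd9 (1.01 ± 0.174). Their list mean was 0.62 (camera adjusted p = 9.92e-07, and 0.0479 with an estimated correlation). Genes associated with quiescence rose in 4 of 13, led by the nuclear receptor gene Nr4a2 (4.81-fold, 2.27 ± 0.371) and Txnip (0.87 ± 0.132), with 4 and 0 over the list alone and a list mean of 0.48 (adjusted p = 0.00135, and 0.0479 with an estimated correlation). Without adult CD48+LSK replicate 2, the adjusted p with an estimated correlation was 0.0988 for both lists. Between 5 and 6 megakaryocyte genes and 2 and 3 quiescence genes rose with 1 array left out.

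Cell cycle genes fell in 5 of 32 measured, and 24 fell and 1 rose over the list alone. The list mean was −0.72 (camera adjusted p = 1.06e-12), and the call was lost with an estimated correlation (adjusted p = 0.23). Bub1, a spindle checkpoint kinase gene, was at −1.51 ± 0.334 (adjusted p = 0.0211), and lost its call without Sox17-labelled replicate 1 (adjusted p = 0.0772) or 2 (adjusted p = 0.07) and without adult CD48+LSK replicate 1 (adjusted p = 0.0771) or 3 (adjusted p = 0.0808), and with only the compared groups in the fit (adjusted p = 0.0848). On adult CD48+LSK replicate 2 the mean of the cell cycle list was −0.40 relative to the other adult CD48+LSK arrays, and without that array 8 of its genes fell. With any 1 array left out the number that fell ran from 0 to 13, and it was 0 without adult CD48+LSK replicate 1 or 3 or without Sox17-labelled replicate 1 or 2.

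Among immediate-early and stress genes 1 rose and 1 fell of 18 measured (4 and 1 over the list alone): Ier3 by 1.32 ± 0.177 and Myc, which fell by 1.87 (SE 0.283) and is also a Wnt target. Their list mean was 0.31 (adjusted p = 0.0119, but adjusted p = 0.57 with an estimated correlation), and without Sox17-labelled replicate 2 it was 0.004 (adjusted p = 0.521). The call was also lost with dim genes left out (adjusted p = 0.238) and with the fry test (adjusted p = 0.326). The mast cell, basophil and eosinophil list (mean −0.44, adjusted p = 0.0301, and adjusted p = 0.0991 with an estimated correlation) had 1 of 11 genes lower, the basophil protease gene Mcpt8 (−2.26 ± 0.401, but adjusted p = 0.0624 with only the compared groups in the fit), with 1 up and 4 down over the list alone. The list lost its call without Sox17-labelled replicate 1 (adjusted p = 0.0610), adult CD48+LSK replicate 1 (adjusted p = 0.0906) or replicate 2 (adjusted p = 0.0615), and in 5 further alternatives (adjusted p = 0.0553 to 0.0847). B cell genes fell in 2 of 11 (3 down and 1 up over the list alone; mean −0.37, adjusted p = 0.0391, and adjusted p = 0.45 with an estimated correlation). Their call was lost without Sox17-labelled replicate 2 (adjusted p = 0.0575) or 3 (adjusted p = 0.0704) and without adult CD48+LSK replicate 1 (adjusted p = 0.235) or 2 (adjusted p = 0.101), and in 6 further alternatives (adjusted p = 0.0553 to 0.673).

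The other 14 lists were not called in this comparison. Among granulocyte and monocyte genes 4 rose and 3 fell of 23 (5 and 5 over the list alone, adjusted p = 0.544): the lysozyme gene Lyz2 (1.56 ± 0.277) and the chemokine receptor gene Ccr2 (2.08 ± 0.381) rose, calls lost with only the compared groups in the fit (adjusted p = 0.0604 and 0.0727), and the myeloid transcription factor genes Cebpa (−1.21 ± 0.146) and Irf8 (−1.19 ± 0.216) fell. Their list mean on adult CD48+LSK replicate 2 was −0.63 relative to the other adult CD48+LSK arrays. Of 17 imprinted growth genes 3 rose and 1 fell (3 and 2 over the list alone, adjusted p = 0.713), with Phlda2 at 1.87 ± 0.276, Mest at 1.25 ± 0.203 and the receptor gene Igf2r at −1.45 ± 0.166. Of 17 Hox and haematopoietic transcription factors 3 rose, Gata2 (1.26 ± 0.156) and Fli1 (0.84 ± 0.159) among them, and 1 fell (the same counts over the list alone, adjusted p = 0.224, and 0.0360 without adult CD48+LSK replicate 3). Among 10 Lin28 and other fetal-stage regulators Plag1 rose (2.37 ± 0.422, but adjusted p = 0.0601 with only the compared groups in the fit), with 1 up and 1 down over the list alone (adjusted p = 0.962).

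Of 12 endoderm genes 1 rose, the chemokine receptor gene Cxcr4 (0.77 ± 0.0950), and 1 fell (adjusted p = 0.962). Erythroid genes rose in 3 of 19, with the water channel gene Aqp1 at 1.52 ± 0.299 (3 and 1 over the list alone, adjusted p = 0.962). Among T and natural killer (NK) cell genes 1 rose and 1 fell of 16 (adjusted p = 0.182, and 0.00645 with the fry test), among stromal and osteoblast genes 2 rose of 13, Sparc among them (2 and 1 over the list alone, adjusted p = 0.824, but 0.0109 with dim genes left out and 0.00162 with the fry test), and among hepatocyte genes 1 fell of 14 (adjusted p = 0.824). Wnt targets fell in 2 of 13 (adjusted p = 0.0838, but 0.0109 with dim genes left out and 0.00799 with the fry test). None of 12 ribosomal protein genes (adjusted p = 0.824), 12 p53 targets (adjusted p = 0.224) or 22 interferon response genes (adjusted p = 0.0643) was called, and 1 of 13 Notch genes rose (adjusted p = 0.0643). The interferon list passed without adult CD48+LSK replicate 2 (adjusted p = 0.0194) or Sox17-labelled replicate 1 (adjusted p = 0.00792) and in 5 further alternatives (adjusted p = 0.0153 to 0.0406), and its mean on adult CD48+LSK replicate 2 was −0.41 relative to the other adult CD48+LSK arrays. The Notch list passed without adult CD48+LSK replicate 2 (adjusted p = 0.0194) or Sox17-labelled replicate 3 (adjusted p = 0.00832), and with a term for Y-linked transcripts (adjusted p = 0.0415). With 1 array left out, 1 to 3 erythroid, 1 or 2 stromal and 0 or 1 Notch genes rose. For imprinted, endoderm and stromal genes the median had the opposite sign to the mean, and for erythroid genes the median and the test were negative and the mean positive.

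**Figure D2:**
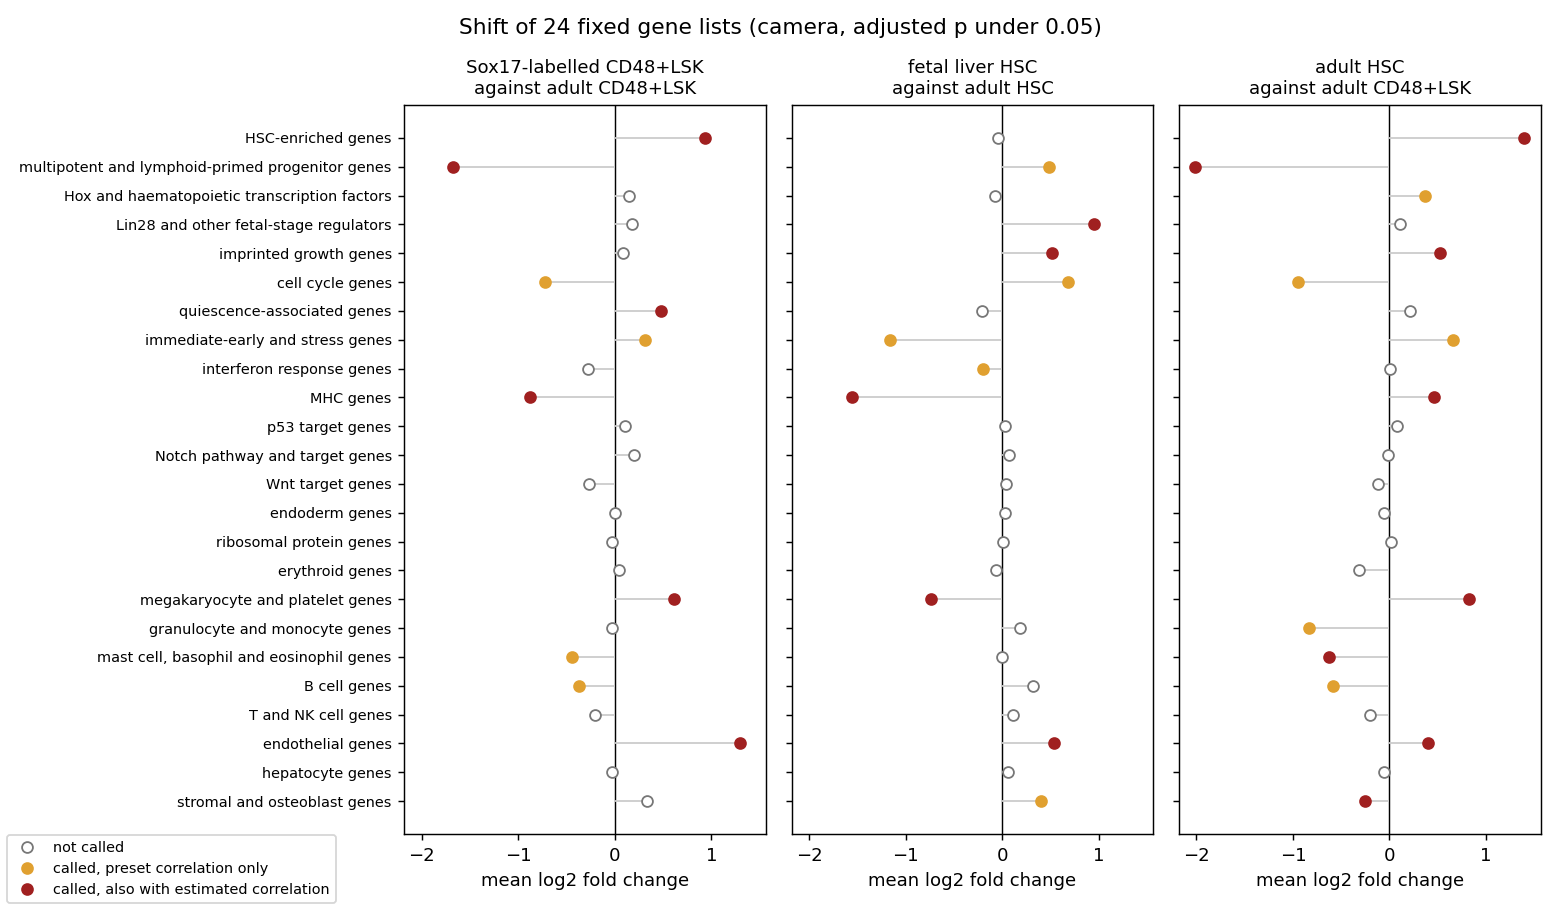
Mean log2 fold change of the measured members of the 24 gene lists in the 3 comparisons; white points were not called, orange points were called by camera with the preset correlation only, and dark red points also with an estimated correlation. In Sox17-labelled against adult CD48+LSK cells 10 lists were called and 6 kept the call, with endothelial genes highest at 1.29 and progenitor genes lowest at −1.68.

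A block of genes at the beta-globin locus rose in the Sox17-labelled cells. These genes lie outside the rule for named genes and were chosen after their values were seen. Olfr631, annotated as an olfactory receptor gene beside the globin genes, rose 212-fold (7.73 ± 0.303), Olfr632 99.4-fold (6.64 ± 0.299), Olfr633 73.3-fold (6.20 ± 0.304), Olfr635 41.5-fold (5.37 ± 0.280), Olfr638 14.4-fold (3.84 ± 0.169) and Olfr639 3.16-fold (1.66 ± 0.284, limma adjusted p = 0.00432). On adult CD48+LSK arrays all of these but Olfr632 (mean 6.26) lay under the array medians, from 3.41 for Olfr631 to 5.39 for Olfr638, so the size of these folds too is uncertain. The embryonic globin gene Hbb-y was at 1.47 ± 0.344 (adjusted p = 0.0298), a call lost without Sox17-labelled replicate 1 (adjusted p = 0.0835) or 2 (adjusted p = 0.114) and without adult CD48+LSK replicate 1 (adjusted p = 0.1) or 3 (adjusted p = 0.0952), and with a term for Y-linked transcripts (adjusted p = 0.0612). Olfr64 was at 0.54 ± 0.113 (adjusted p = 0.0154). Its call was lost without adult CD48+LSK replicate 3 (adjusted p = 0.0735) or Sox17-labelled replicate 2 (adjusted p = 0.0685) or 3 (adjusted p = 0.0582). It was also lost with only the compared groups in the fit (adjusted p = 0.0917). In all, 8 of the 21 genes tested in this window rose, while the embryonic genes Hbb-bh1 (0.01 ± 0.110) and Hbb-bh2 (−0.23 ± 0.189) were not called. Both probe sets annotated to the adult beta-globin genes together were higher, by 3.56 ± 0.425 (adjusted p = 0.000717) and 3.49 ± 0.315 (adjusted p = 9.67e-05). Both probe sets for the alpha-globin genes together were not (0.20 ± 0.291 and 0.28 ± 0.309, adjusted p = 0.847 and 0.788).

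**Figure D3:**
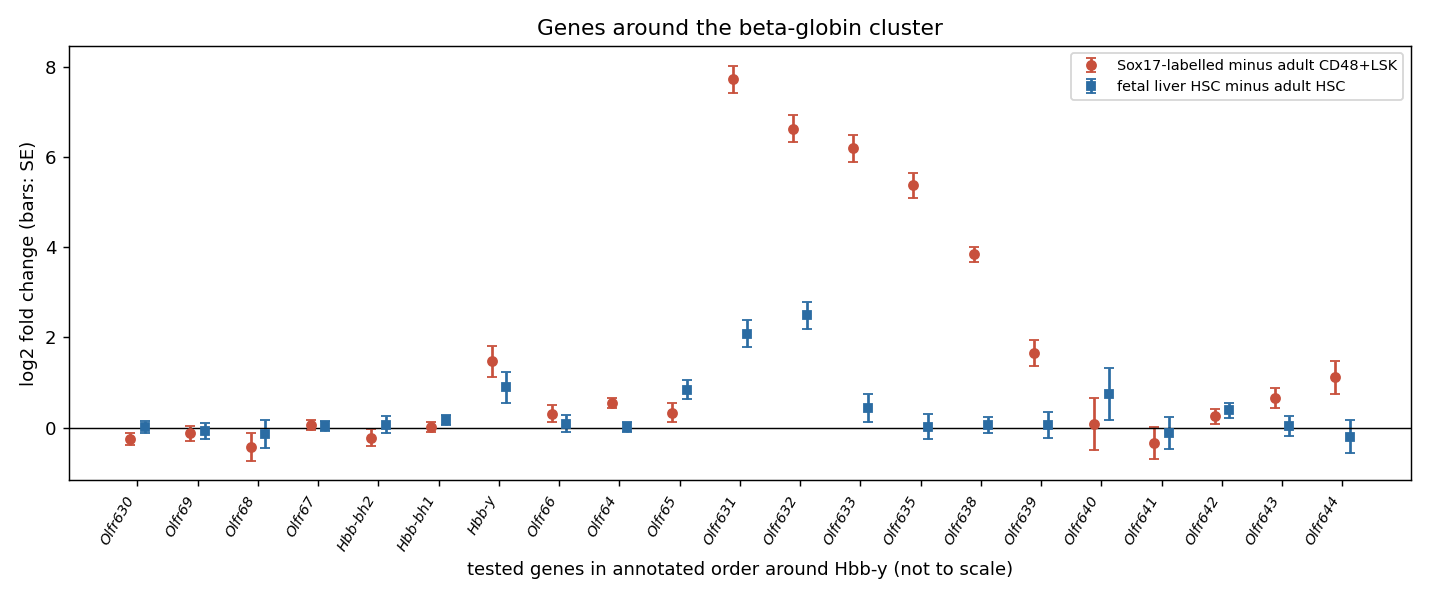
Log2 fold change with SE of the 21 tested genes around Hbb-y in annotated order, for Sox17-labelled against adult CD48+LSK cells (red circles) and fetal liver against adult HSCs (blue squares), n = 3 arrays per group. From Olfr631 to Olfr639 the Sox17-labelled change ran from 7.73 to 1.66. In all, 8 of the 21 genes rose, with Hbb-y (1.47) and Olfr64 (0.54) the smallest.

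In total 961 of 19938 genes (4.82%) passed in this comparison (limma, Benjamini-Hochberg), 595 higher and 366 lower, and 531 of them changed at least 2-fold. Without adult CD48+LSK replicate 2, 1070 genes passed, 483 higher and 587 lower, of which 464 and 322 were among the calls above. The genes lower numbered 232 without adult CD48+LSK replicate 1, 229 without replicate 3 and 228 without Sox17-labelled replicate 2, with 527, 495 and 495 higher. Fitting only the 6 arrays compared gave 618 genes, and weighting arrays by quality gave 2052, 901 higher and 1151 lower. Transplanted cells were set against cells of untransplanted 8-week mice and no transplanted control without Sox17 was analysed here, so transplantation, the virus and Sox17 are not separated.

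Fetal liver and adult HSCs of the same surface phenotype were compared to find how stem cells differ between the stages. Fetal HSCs had more Bank1, a B cell scaffold protein gene (11.4-fold, log2 3.51 ± 0.240, SE, n = 3 per group), and more of the matrix protein gene Postn (9.59-fold, 3.26 ± 0.220). The guanine exchange factor gene Rasgrp3 (2.84 ± 0.295), the growth factor gene Pdgfc (2.65 ± 0.302), Wfdc17 (2.90 ± 0.377) and Wfdc18 (2.50 ± 0.243) also rose. The chitinase-like gene Chil5 was at 2.98 ± 0.550 (limma adjusted p = 0.0108), a call lost without adult HSC replicate 3 (adjusted p = 0.0584). Rgs1, a regulator of G protein signalling, was 36.1-fold lower in fetal HSCs (−5.17 ± 0.370), the class II gene H2-Aa 14.7-fold (−3.87 ± 0.299) and the retinaldehyde dehydrogenase gene Aldh1a1 13.4-fold (−3.75 ± 0.279). Tmem273 (−3.74 ± 0.466), the protease inhibitor gene Serpinb1a (−3.20 ± 0.323), H2-Q5 (−3.19 ± 0.168) and H2-Ab1 (−3.13 ± 0.157) fell as well. The myosin light chain gene Myl10 was at −3.14 ± 0.649 (adjusted p = 0.0219, the largest of the 8 rises and 8 falls). Its call was lost without fetal liver HSC replicate 1 (adjusted p = 0.0855) or 2 (adjusted p = 0.0755) and without adult HSC replicate 1 (adjusted p = 0.0833) or 2 (adjusted p = 0.086). Lin28b, described next, completes the rises. For 11 of these 16 genes, including Bank1, Postn, Rgs1, H2-Aa and Aldh1a1, the lower group mean lay under all array medians, so the size of the change is uncertain.

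Fetal-stage regulators rose in 5 of 10 measured, with 0 falling (7 and 0 over the list alone). Lin28b, the RNA-binding repressor of let-7 microRNAs, rose by 2.44 ± 0.278, the chromatin protein gene Hmga2 4.29-fold (2.10 ± 0.190), while the RNA-binding protein genes Igf2bp1 (1.78 ± 0.216) and Igf2bp3 (1.65 ± 0.114) also rose. The list mean was 0.95 (camera adjusted p = 2.47e-08, and 0.00347 with an estimated correlation). Imprinted growth genes rose in 5 of 17 (11 up and 2 down over the list alone), among them the fetal growth factor gene Igf2 (2.16 ± 0.347), Peg3 (1.14 ± 0.152) and Igf2r (1.08 ± 0.166), with a list mean of 0.52 (adjusted p = 1.11e-05, and 0.0276 with an estimated correlation). In the leave-outs 5 fetal-stage regulators and 3 to 5 imprinted genes rose. In adult HSCs Lin28b (mean 4.41), Igf2bp1 (4.92), Igf2bp3 (5.73) and Igf2 (5.38) were dim, so the size of their changes is uncertain.

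MHC genes fell in 6 of 9 (6 over the list alone), with a mean of −1.56 (adjusted p = 9.53e-17, and 0.00148 with an estimated correlation); besides H2-Aa and H2-Ab1, the invariant chain gene Cd74 (−1.67 ± 0.174) and H2-Eb1 (−1.58 ± 0.156) were lower. Megakaryocyte and platelet genes fell in 4 of 17 (11 down and 1 up over the list alone), with the platelet chemokine gene Pf4 4.69-fold lower (−2.23 ± 0.275), Plek at −1.76 ± 0.306 and the integrin gene Itga2b at −1.50 ± 0.161 (mean −0.73, adjusted p = 3.04e-11, and 0.0151 with an estimated correlation). Endothelial genes rose in 4 of 21 (7 over the list alone), Egfl7 (4.50-fold, 2.17 ± 0.148) and Cdh5 (1.39 ± 0.249) among them, with a mean of 0.53 (adjusted p = 7.23e-06, and 0.00634 with an estimated correlation). Cdh5 in adult HSCs (mean 4.84) and Cd74 in fetal liver HSCs (5.24) were dim. Across the leave-outs 6 MHC and 3 or 4 megakaryocyte genes fell and 2 to 4 endothelial genes rose.

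For 5 further lists the call was lost with an estimated correlation. Cell cycle genes rose in 4 of 32 and in 22 over the list alone (mean 0.68, adjusted p = 8.22e-13, and adjusted p = 0.218 with an estimated correlation). Immediate-early genes fell in 6 of 18 and in 9 over the list alone (mean −1.16, adjusted p = 9.73e-11, and adjusted p = 0.127 with an estimated correlation), with Myc 3.52-fold lower (−1.81 ± 0.283). Progenitor genes rose in 3 of 15, Flt3 (1.52 ± 0.151) and the chromatin organizer gene Satb1 (1.72 ± 0.203) among them, and 1 fell (6 and 1 over the list alone, mean 0.49, adjusted p = 0.00122, and adjusted p = 0.095 with an estimated correlation). Stromal genes rose in 2 of 13, Postn among them (3 over the list alone, mean 0.40, adjusted p = 0.0238, and adjusted p = 0.095 with an estimated correlation), a call also lost without adult HSC replicate 2 (adjusted p = 0.0697), with dim genes left out (adjusted p = 0.781) or with only the compared groups in the fit (adjusted p = 0.0712). Interferon genes fell in 4 of 22 (4 over the list alone), the peptide transporter gene Tap1 (−1.01 ± 0.167) among them, with a mean of −0.20 (adjusted p = 0.00667, and adjusted p = 0.579 with an estimated correlation). The interferon call was lost without fetal liver HSC replicate 1 (adjusted p = 0.0854) or 2 (adjusted p = 0.393) and with the fry test (adjusted p = 0.488). With 1 array left out, the genes called numbered 0 to 2 for the cell cycle, 1 to 6 for the immediate-early list, 1 to 6 for interferon, 2 or 3 rises for the progenitor list and 1 to 3 for stromal genes.

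The other 14 lists were not called between fetal liver and adult HSCs. In the HSC list 1 gene rose and 3 fell of 21, the sulfotransferase gene Sult1a1 (−1.53 ± 0.208), Clec1a (−1.49 ± 0.154) and Fhl1 (−1.01 ± 0.183), with 6 up and 7 down over the list alone (adjusted p = 0.294). Among Hox and haematopoietic transcription factors 3 rose, the repressor gene Gfi1 (1.02 ± 0.164) among them, and 2 fell of 17 (3 and 4 over the list alone, adjusted p = 0.0712), with 1 or 2 rising and 0 or 1 falling when an array was left out. That list passed without adult HSC replicate 1 (adjusted p = 0.0177), with array weights (adjusted p = 0.0429) and with quantile normalization again (adjusted p = 0.0334). The cyclin-dependent kinase inhibitor gene Cdkn2c of the quiescence list fell (−2.08 ± 0.286), as did the erythroid and megakaryocyte factor gene Gfi1b (−1.36 ± 0.224). For the HSC and erythroid lists the mean and the test were negative and the median positive, and for ribosomal protein and mast cell genes the test was negative with a positive mean and median.

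Between fetal liver and adult HSCs 621 genes (3.11%) passed, 272 higher and 349 lower, and 325 changed at least 2-fold. The count fell to 411 without fetal liver HSC replicate 1, 407 without replicate 2, 422 without adult HSC replicate 1, 364 without adult HSC replicate 2 and 370 without adult HSC replicate 3. Tissue and age both differed between the groups. The Xist and Eif2s3y levels given above varied widely among the adult HSC arrays, and the fetal values lay within that range.

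Adult HSCs were compared with adult CD48+LSK cells to give the stem cell to progenitor difference within adult marrow. Abcg3, a transporter gene, was 9.96-fold higher in HSCs (log2 3.32 ± 0.267, SE, n = 3 per group), Akr1c19 8.34-fold (3.06 ± 0.315), Mmrn1 7.85-fold (2.97 ± 0.245) and Plxdc2 7.34-fold (2.88 ± 0.251). Slamf1, whose product CD150 was used to sort the HSCs, rose 6.21-fold (2.64 ± 0.173), the stress-response gene Nupr1 6.48-fold (2.70 ± 0.186), the guanine deaminase gene Gda 6.47-fold (2.69 ± 0.230) and the guanylate-binding protein gene Gbp9 6.29-fold (2.65 ± 0.424). Dntt was 85.9-fold lower in HSCs (−6.42 ± 0.212), the carbonic anhydrase gene Car1 54.5-fold (−5.77 ± 0.341), the myeloperoxidase gene Mpo 37.4-fold (−5.22 ± 0.407) and the cathepsin G gene Ctsg 31.2-fold (−4.96 ± 0.657). Cd48, the sorting marker, was 39.1-fold lower (−5.29 ± 0.595). Tespa1 (−4.37 ± 0.394), Cd52 (−4.02 ± 0.410) and Atp8b4 (−3.99 ± 0.370) fell too, and the largest limma adjusted p among these 16 genes was 0.00427, for Gbp9. For 12 of them the lower group mean lay under all array medians, the exceptions being Abcg3, Plxdc2, Nupr1 and Cd52, so the size of those 12 changes is uncertain.

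HSC-list genes rose in 18 of 21 (20 over the list alone), with Mllt3 (1.94 ± 0.169), Pdzk1ip1 (1.51 ± 0.139) and Clec1a (1.36 ± 0.154) beside Slamf1, and a list mean of 1.40 (camera adjusted p = 1.08e-33, and 0.00041 with an estimated correlation). Progenitor genes fell in 9 of 15 (12 over the list alone), including Satb1 (−2.88 ± 0.203), Flt3 (−2.82 ± 0.151) and Cd244a (−2.78 ± 0.157), with a mean of −2.01 (adjusted p = 4.81e-22, and 0.000834 with an estimated correlation). When an array was left out, 14 to 18 HSC-list genes rose and 9 or 10 progenitor genes fell. Cd48, Cd34, Flt3 and Slamf1 define or follow the sort, so their direction is not independent of it.

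Megakaryocyte and platelet genes rose in 8 of 17 (13 up and 1 down over the list alone), Mmrn1 and Pf4 (6.20-fold, 2.63 ± 0.275) among them, with a mean of 0.82 (adjusted p = 8.42e-12, and 0.0162 with an estimated correlation). Endothelial genes rose in 6 of 21 (8 and 1 over the list alone), with the angiopoietin receptor gene Tek at 1.81 ± 0.266, Esam at 1.55 ± 0.198 and Tie1 at 1.20 ± 0.111 (mean 0.40, adjusted p = 0.000246, and 0.0162 with an estimated correlation). Imprinted growth genes rose in 6 of 17 (7 and 1 over the list alone), Grb10 (1.85 ± 0.173), Phlda2 (1.49 ± 0.276) and Sgce (1.11 ± 0.167) among them (mean 0.52, adjusted p = 0.000174, and 0.0363 with an estimated correlation). MHC genes rose in 3 of 9 (3 over the list alone), with H2-Aa at 1.69 ± 0.299 (mean 0.46, adjusted p = 3e-04, and 0.0348 with an estimated correlation). Without adult CD48+LSK replicate 2, the adjusted p with an estimated correlation was 0.0742 for the MHC list. With 1 array left out, 2 to 6 megakaryocyte, 3 to 6 endothelial, 3 to 5 imprinted and 1 to 3 MHC genes rose; without adult HSC replicate 2, Cd74 (adjusted p = 0.0532) and H2-Eb1 (adjusted p = 0.0588) were the MHC genes that lost the call.

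Among mast cell, basophil and eosinophil genes Mcpt8 fell (−3.48 ± 0.401), 1 of 11 (1 over the list alone, mean −0.63, adjusted p = 0.00076, and 0.0279 with an estimated correlation). No stromal gene of 13 was called over all genes and 1 fell over the list alone, with a list mean of −0.25 (adjusted p = 0.00287, and 0.0348 with an estimated correlation). The stromal call was lost with dim genes left out (adjusted p = 0.166), and without adult CD48+LSK replicate 2 its adjusted p with an estimated correlation was 0.0889. Cell cycle genes fell in 13 of 32 and in 28 over the list alone, the ribonucleotide reductase gene Rrm2 (−1.13 ± 0.171) among them, with a mean of −0.95 (adjusted p = 2.35e-23). With an estimated correlation, that list's adjusted p was 0.0709, and without adult CD48+LSK replicate 2 15 of its genes fell. Granulocyte and monocyte genes fell in 5 of 23 (5 over the list alone), Mpo, Ctsg and Cebpa (−0.998 ± 0.146) among them (mean −0.83, adjusted p = 1.69e-06, and adjusted p = 0.0961 with an estimated correlation), and in 7 without adult CD48+LSK replicate 2. With 1 array left out, 1 to 15 cell cycle genes fell, 1 of them without adult HSC replicate 3, and 3 to 7 granulocyte and monocyte genes fell.

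B cell genes fell in 2 of 11 (3 over the list alone, mean −0.59, adjusted p = 4e-05, and adjusted p = 0.0961 with an estimated correlation), and in 0 to 4 with 1 array left out. Hox and haematopoietic transcription factors rose in 3 of 17 (7 over the list alone), with Hoxa5 at 0.99 ± 0.166 and Gata2 at 1.10 ± 0.156 (mean 0.37, adjusted p = 1.95e-06, and adjusted p = 0.0961 with an estimated correlation), and 2 to 4 rose with 1 array left out. Immediate-early genes had 0 of 18 called and 2 higher over the list alone (mean 0.66, adjusted p = 0.000246, and adjusted p = 0.303 with an estimated correlation or 0.129 with the fry test). The other 11 lists were not called, with the quiescence list closest (2 of 13 rose, adjusted p = 0.0572); it passed without adult HSC replicate 2 (adjusted p = 0.0223) or adult CD48+LSK replicate 1 (adjusted p = 0.0443) and in 3 further alternatives (adjusted p = 0.0365 to 0.0457), although 0 or 1 of its genes rose with 1 array left out. The T and NK cell list passed without adult CD48+LSK replicate 3 (adjusted p = 0.0319) and with the fry test (adjusted p = 0.0115), and the endoderm list with dim genes left out (adjusted p = 0.0173) or the term for Y-linked transcripts (adjusted p = 0.0404). Median, mean and test differed in sign for the Lin28, interferon, Notch and endoderm lists, none of them called.

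Between adult HSCs and adult CD48+LSK cells 732 genes (3.67%) passed, 448 higher and 284 lower, and 389 changed at least 2-fold. Without adult CD48+LSK replicate 2, 661 genes passed, 305 higher and 356 lower, while without adult HSC replicate 2 the count was 410 (244 and 166) and without adult HSC replicate 3 it was 352 (233 and 119). It was 533 (367 and 166) without adult CD48+LSK replicate 1 and 524 (362 and 162) without replicate 3. Array weights gave 1608 genes, 787 higher and 821 lower. Y-linked transcripts were higher on the adult HSC arrays than on adult CD48+LSK replicates 1 and 3, and with a term for these transcripts, added after the data were seen, 469 genes passed, 360 higher and 109 lower.

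The change in Sox17-labelled cells was then set beside the fetal and the stem cell differences, to see whether it ran along either. Genes that rose both in Sox17-labelled cells and in adult HSCs against adult CD48+LSK cells numbered 162, Mllt3, Tek, Esam and Mmrn1 among them, against 13.4 for independent lists. Genes lower in both numbered 136, Dntt, Cd52, Cd244a and Flt3 among them, against 5.21. Only 8 and 12 genes were called in opposite directions (8.48 and 8.22 for independent lists). These counts without adult CD48+LSK replicate 2 were 106 higher in both, 199 lower in both and 22 opposite. Across 19938 genes, which are not independent replicates, Pearson's r was 0.462 and Spearman's rho 0.496. Both comparisons use the same 3 adult CD48+LSK arrays, and unchanged groups simulated against these arrays gave a mean r of 0.535 (0.0111 to 0.937 in 95% of 1000 draws). The observed covariance was 0.0745 against a simulated 0.0259, a difference of 0.0486. The observed covariance lay within the simulated range of 0.000289 to 0.106. Part of the overlap may come from the shared arrays. With these arrays split so that 1 served one comparison and the other two the other, a test added after the data were seen, the mean r over 6 splits was 0.261 (0.154 to 0.343) and the mean rho 0.125 (−0.00014 to 0.241). A lone array was then assumed to vary like the other groups and is noisier than a mean, so how much of the drop is due to sharing is open. Genes higher in both numbered 33 to 149 in these splits (1.59 to 23.3 for independent lists), genes lower in both 31 to 69 (0.643 to 14.5) and opposite calls 6 to 49.

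Against the fetal minus adult HSC difference, with which it shares no array, the Sox17-labelled change had no overall relation across genes (r = −0.00955, rho = −0.0652, covariance −0.00145; simulated r 0.00339, −0.132 to 0.137). Of 183 genes called in both, 97 moved the same way. The 39 genes higher in both (8.12 for independent lists) included Rasgrp3 (4.33 ± 0.295 and 2.84 ± 0.295), the LIM domain-binding protein gene Ldb2 (4.32 ± 0.310 and 1.76 ± 0.310), Nrep (3.38 ± 0.275 and 1.80 ± 0.275), the catenin-like gene Ctnnal1 (2.72 ± 0.156 and 1.77 ± 0.156) and Egfl7 (2.07 ± 0.148 and 2.17 ± 0.148). Chil5 was also called in both (2.65 ± 0.550, adjusted p = 0.0147, in Sox17-labelled cells), a call lost there without adult CD48+LSK replicate 3 (adjusted p = 0.0691), without Sox17-labelled replicate 2 (adjusted p = 0.0516) or 3 (adjusted p = 0.0528) and with only the compared groups in the fit (adjusted p = 0.0812). The 58 lower in both (6.41 for independent lists) included H2-Ab1, H2-Aa, Tmem273, Nkg7 and the adhesion molecule gene Alcam (−2.35 ± 0.299 and −2.19 ± 0.299). Myl10 was called lower in both (−2.67 ± 0.649, adjusted p = 0.0361, in Sox17-labelled cells), but 5 of the 6 leave-outs lost that call (adjusted p = 0.0732 to 0.133), as did only the compared groups in the fit (adjusted p = 0.0676) and eBayes with trend and robust (adjusted p = 0.0573). Another 54 genes were higher in Sox17-labelled cells and lower in fetal HSCs (10.4), among them Mmrn1 and Gata2, and 32 were lower in Sox17-labelled cells and higher in fetal HSCs (4.99), among them Wfdc17, Flt3 and Igf2r. Opposite calls thus exceeded independent lists too, so the excess of genes called the same way does not show a shared direction. Independent lists were counted over all genes with no filter on intensity. The numbers without adult CD48+LSK replicate 2 were 41 higher in both, 82 lower in both and 111 opposite. Mmrn1 lost its fetal call without fetal liver HSC replicate 2 or adult HSC replicate 1 (adjusted p = 0.0503 each), and Gata2 without fetal liver HSC replicate 1 (adjusted p = 0.0503) or adult HSC replicates 2 (adjusted p = 0.0541) and 3 (adjusted p = 0.0580).

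**Figure D4:**
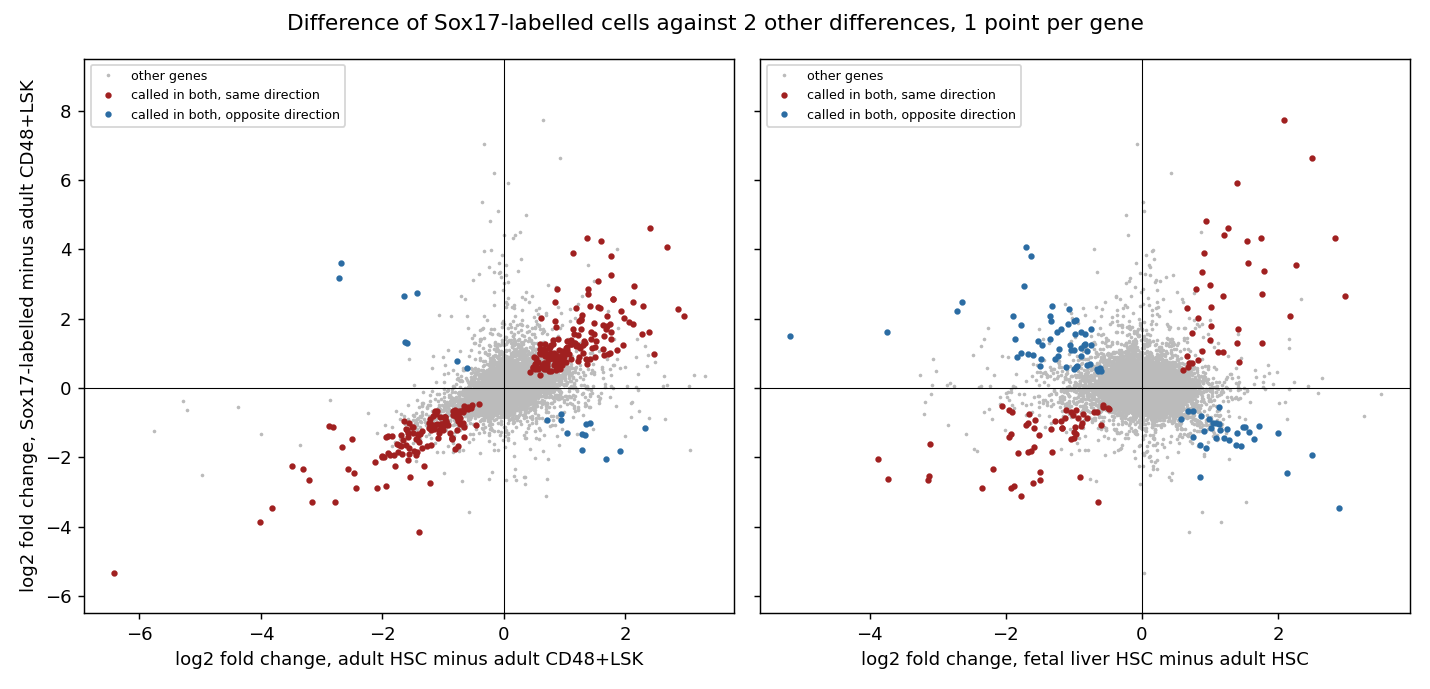
Log2 fold change of each of 19938 genes in Sox17-labelled against adult CD48+LSK cells, plotted against adult HSC minus adult CD48+LSK (left) and against fetal liver HSC minus adult HSC (right); red genes were called in both in the same direction and blue genes in opposite directions. On the left, where the comparisons share 3 arrays, r was 0.462 with 298 of 318 shared calls in the same direction, and on the right r was −0.00955 with 97 of 183.

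The 200 genes most significantly higher in fetal liver HSCs had a mean change of 0.25 in Sox17-labelled cells, with 34 called higher and 28 lower (camera p = 0.0659, and 0.447 with an estimated correlation). The 200 most significantly lower had a mean of −0.03, with 37 higher and 39 lower (p = 0.726, and 0.899 with an estimated correlation). With 100 genes a set, the fetal-higher set passed (mean 0.45, p = 0.000279), and this call was lost with an estimated correlation (p = 0.118). With 500 genes the mean of the fetal-higher set was 0.103, and the set did not pass. The median change of the fetal-higher set was 0.02 with 200 genes, 0.103 with 100 and −0.01 with 500. Its typical gene thus changed less than the mean. A fetal score was the mean of the 272 genes called higher in fetal HSCs minus the mean of the 349 called lower, set to 0 on the adult CD48+LSK arrays. As a mean over genes, the score can be moved by a few large changes, and no median was taken. It was 0.26 ± 0.068 (SD, n = 3) in Sox17-labelled cells and 0.00 ± 0.041 in adult CD48+LSK cells. All 3 Sox17-labelled arrays (0.18, 0.29 and 0.30) lay above the adult CD48+LSK arrays (−0.04, 0.05 and −0.01), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Fetal liver and adult HSCs, on which the genes were chosen, were at 1.63 ± 0.181 and −0.71 ± 0.029, a gap of 2.34. Adult CD48+LSK cells thus lay further above adult HSCs than Sox17-labelled cells lay above adult CD48+LSK cells. A shift in the score is therefore not specific to the fetal stage. With only the compared groups in the fit, Sox17-labelled cells lay 0.09 above adult CD48+LSK cells (exact permutation p = 0.4). Without adult HSC replicate 3 this difference was 0.52.

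**Figure D5:**
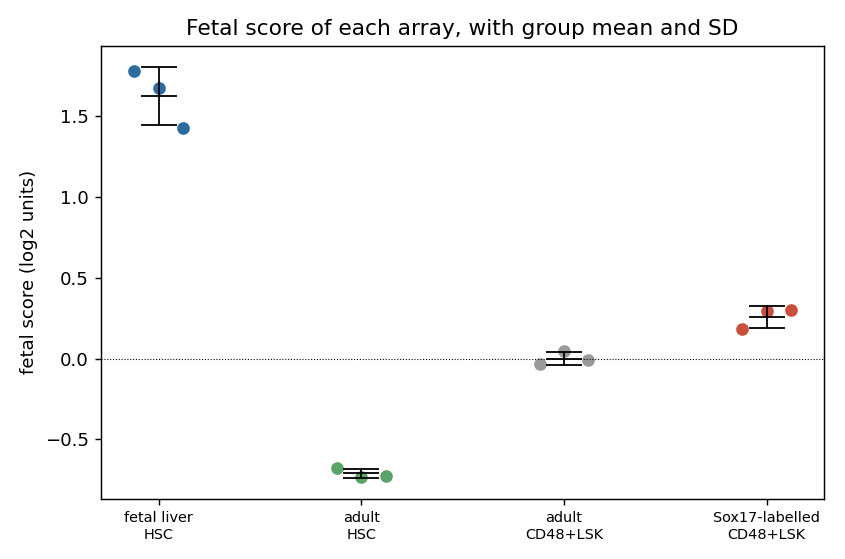
Fetal score of each array on the log2 scale, centred on the adult CD48+LSK mean, with points for arrays and bars for the group mean and SD (n = 3). Sox17-labelled arrays lay at 0.18 to 0.30 and adult CD48+LSK arrays near 0. Adult HSC arrays had a mean of −0.71 and fetal liver HSC arrays of 1.63, and the genes were chosen on these 2 groups.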

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

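The tests of cross-hybridisation, fetal-stage expression, endothelial cells, adult-type HSCs and sex-linked probe sets described here were chosen after the result was seen. Probe sets that the gene tests did not use also differed from adult CD48+LSK cells. Of 1621 probe sets annotated to several genes, 22 were higher and 27 lower in Sox17-labelled cells, and the adult beta-globin probe sets led the higher ones. Of 5530 probe sets not in the annotation, 39 were higher and 39 lower, the highest by 4.92 ± 0.230 on the log2 scale (limma adjusted p = 5.07e-07). Between fetal liver and adult HSCs the corresponding counts were 11 higher and 30 lower, and 17 higher and 35 lower.

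The beta-globin probe sets and 8 of 21 tested neighbours, Olfr631 and Olfr632 foremost, were higher in Sox17-labelled cells. Cross-hybridisation across olfactory receptor probe sets in general is argued against by the 1009 olfactory receptor genes elsewhere, whose median change was −0.0793 with 3 higher and 2 lower. Genes elsewhere cannot test cross-hybridisation among the neighbouring probe sets of Olfr631 to Olfr639, which stays open. RNA from red cells would bring alpha-globin. Its mean change was 0.24 with an upper 95% limit of 0.902, under the 1.76 that is 50% of the beta-globin change. The alpha-globin probe sets read 6.06 and 5.77 in adult CD48+LSK cells, near the array medians (5.87 to 5.94). The beta-globin probe sets read 9.3 and 9.27 there. Whether the alpha-globin probe sets respond to red cell RNA as strongly was not tested, so RNA from red cells stays open. Between fetal liver and adult HSCs the alpha-globin probe sets were at 1.27 and 1.26 (limma adjusted p = 0.0509 and 0.0686). The beta-globin probe sets were at 3.12 and 3.08 there. Fetal-stage expression of the locus cannot be told apart, because 2 of the 8 risers (Olfr631 by 2.08 ± 0.303 and Olfr632 by 2.50 ± 0.299) and the beta-globin probe sets were also higher in fetal than adult HSCs, while the other 6 were not called there. A locus-wide response to Sox17 or a proviral insertion near the locus in a dominant clone may also be involved, and neither was tested.

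Endothelial genes were higher in Sox17-labelled cells, with Cdh5 at 10.68 against 4.77 in adult CD48+LSK cells. Endothelial cells in the sort, which used the LSK gate (lineage-negative, Sca1+ and Kit+), were tested on the 21 list members. An upper 95% limit under a doubling was found for 10 of them. Among these were Kdr (4.89 against 5.02), Flt1 (5.11 against 5.03) and Plvap (5.57 against 5.45), which endothelium expresses strongly. Kdr, Flt1 and Plvap were dim in both groups, and whether their probe sets respond to endothelial RNA was not tested. Robo4 counts among the 10 although it was called higher (0.61, limma adjusted p = 0.0385). These values argue against endothelial cells only as far as such probe sets respond. More adult-type HSCs in the gate are argued against as the only source of the 8 of 10 risers that exceeded their level in adult HSCs, such as Egfl7. The risers were chosen on the same Sox17-labelled arrays. Among the 11 HSC-list risers 2 exceeded that level, and among all 595 genes that rose 279 did. More such cells in the gate beside another source therefore stay open. A response of part of the endothelial programme to Sox17 may be the source, as a hypothesis found on these data and not tested. Transplantation and the virus, for which no control was analysed here, stay open.

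Adult CD48+LSK replicate 2 stood apart from its group. A narrower range of values alone is argued against by its rank correlations with its group, at most 0.955, while the other within-group pairs had at least 0.98. Sex-linked genes alone are argued against by its Pearson correlations without the 1031 probe sets annotated to X or Y genes, at most 0.973 against at least 0.984, although these were at most 0.967 with them, so those probe sets may hold part of the gap. For cells of another type in the sort, the highest of the cell type lists was 0.0626 above the other arrays of the group. That test looked only for lists that were higher. The granulocyte and monocyte list was at −0.63 relative to those arrays, so a different mix of cells stays open. Over the 19938 genes tested the gap was small (at most 0.982 against 0.984), and RNA quality was not tested.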

How the results depend on the processing

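The repeated quantile normalization, the term for Y-linked transcripts and the split of the shared arrays were chosen after seeing the data, and the remaining alternatives before. None of the named genes and lists reversed direction past the threshold under any alternative that was run. For named genes, 1811 of 1954 values kept their side of the threshold in the Sox17-labelled comparison (111 lost and 32 gained the call), 1679 of 1849 between fetal liver and adult HSCs (156 and 14) and 1626 of 1752 between adult HSCs and adult CD48+LSK cells (85 and 41). For the lists these were 390, 417 and 415 of 431 values each. Causes below were not tested unless stated.

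The count for Sox17-labelled against adult CD48+LSK cells, 961, was 618 with only the compared groups in the fit, which has fewer arrays to estimate the spread. With array weights, under which adult CD48+LSK replicate 2 had 0.288 and the others 0.789 to 3.31, it was 2052 with 43.9% higher (61.9% as designed), and the count between adult HSCs and adult CD48+LSK cells, 732, was 1608 with 48.9% higher (61.2%). With the term for Y-linked transcripts the latter was 469 with 76.8% higher, and the correlation of the Sox17-labelled change with the adult HSC difference was 0.337. With the shared adult CD48+LSK arrays split it was 0.261, against 0.462 with them shared. A minimum log2 change of 1 left 531, 325 and 389 genes by construction. With an estimated correlation 6, 5 and 8 lists were called. The shift of the fetal-higher set, 0.254 (p = 0.0659 with limma's camera at the preset correlation), passed the threshold with sets of 100 genes (0.453, p = 0.000279) and with median centring (0.278, p = 0.0244). For the sets of 100 genes the call was lost with an estimated correlation (p = 0.118).

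The fetal score of 0.258 was 0.191 with all probe sets, 0.154 with cyclic loess and 0.154 with quantile normalization again, 0.317 with median centring, 0.093 with only the compared groups (exact permutation p = 0.4), 0.197 with array weights and 0.439 with genes of at least 2-fold change; the cause was not tested. With the dim genes left out the Sox17 probe set gave no value.

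Leaving out 1 array gave 703 to 1070 genes in the Sox17-labelled comparison, 364 to 612 between fetal liver and adult HSCs and 352 to 661 between adult HSCs and adult CD48+LSK cells; the cause was not tested. The correlations ran from −0.0342 to 0.00523 (fetal difference) and 0.423 to 0.507 (HSC difference), the fetal score from 0.163 to 0.52, the fetal-higher set from 0.152 to 0.35 and the fetal-lower set from −0.119 to 0.022. The numbers of lists called ran from 8 to 11, 9 to 11 and 13 to 14.

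Replicate numbers did not pair the arrays: the 18 same-number pairs had correlations of deviations from −0.18 to 0.099, 0 of them over 0.1, the 36 other pairs from −0.118 to 0.142, and 5 of 12 arrays correlated best with their own number. With the replicate block, 925, 578 and 713 genes passed and the fetal score was 0.174.

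Other splits of the 6 arrays of each comparison are too few (10) for a share under 0.05. Only 1 split of each, the real one, gave as many genes, with 961, 621 and 732 against a highest other of 0, 0 and 2. Every other split mixed the compared groups, so any difference between them widened the spread and lowered the count. The splits therefore decide nothing.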

Other observations

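The genes named here were chosen after their values were seen, and the test of neighbouring genes was planned before. Sox17-labelled cells also differed from adult HSCs, with 382 genes higher and 435 lower (limma, Benjamini-Hochberg over 19938 genes). Krt24 was higher than in adult HSCs by 7.37 ± 0.158 (adjusted p = 1.86e-10), from a dim mean of 4.25 there, while the HSC transcription factor gene Hlf was lower (−0.67 ± 0.105, adjusted p = 0.00269), as was the guanine exchange factor gene Fgd5 (−0.58 ± 0.128, adjusted p = 0.0247). Mecom, another HSC transcription factor gene, rose against adult CD48+LSK cells (1.85 ± 0.278, adjusted p = 0.00176) and was at −0.28 ± 0.278 against adult HSCs (adjusted p = 0.793).

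Some neighbouring genes rose in Sox17-labelled against adult CD48+LSK cells, and no test of gene families was run. Of the Gimap genes, which encode GTPases of lymphocytes, Gimap4 rose by 4.23 ± 0.204 (limma adjusted p = 1.05e-07), Gimap9 by 1.58 ± 0.106 (adjusted p = 2.23e-06), Gimap8 by 1.39 ± 0.241 (adjusted p = 0.0047) and Gimap6 by 1.23 ± 0.137 (adjusted p = 0.000184). Gimap1 (0.86 ± 0.156, adjusted p = 0.00627) and Gimap5 (0.85 ± 0.176, adjusted p = 0.015) rose less, Gimap7 fell by 1.45 (SE 0.229, adjusted p = 0.00254) and Gimap3 was not called (−0.54 ± 0.401, adjusted p = 0.622). The inflammasome sensor genes Naip2 (1.69 ± 0.154, adjusted p = 3.86e-05), Naip5 (2.11 ± 0.206, adjusted p = 6.55e-05) and Naip6 (2.84 ± 0.329, adjusted p = 0.000251) rose, as did their annotated neighbours Ocln (1.03 ± 0.169, adjusted p = 0.00312) and Marveld2 (0.90 ± 0.188, adjusted p = 0.0156). Each value comes from 3 arrays per group, and these genes were not refitted with arrays left out.

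A hypothesis is that local clusters of genes rose together in Sox17-labelled cells. Among 19917 genes in annotated order, 64 neighbouring pairs were both called higher, against a mean of 17.6 (10 to 26) in 1000 shuffles of the calls. Pairs called lower numbered 25 (6.73 by shuffling, 2 to 12). The excess is not particular to this comparison: pairs higher in fetal HSCs numbered 12 (3.7, 0 to 8) and pairs lower 34 (6.12, 2 to 12), and pairs higher in adult HSCs than adult CD48+LSK cells 24 (10.1, 4 to 16). Shared regulation of neighbours and cross-hybridisation between similar neighbouring genes may both contribute, and the shuffles do not separate them. The shuffles also moved calls over all placed genes with no filter on intensity. Neighbouring genes that are merely expressed together could thus give an excess too.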
